A study of Caenorhabditis elegans with 47 samples.

How the data were processed

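RNA of Caenorhabditis elegans was measured on 47 Affymetrix arrays, with 1 array per sample. Per the labels, the worms expressed GFP, GFP::degron or Abeta, and the samples of a genotype and time were biological repeats. Per the labels' protocols, worms grew on NGM plates with a lawn of OP50 bacteria, RNA was extracted with an RNeasy kit, and 5 µg of total RNA per sample was turned into biotin-labelled cRNA.

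The deposited values are linear intensity summaries of each probe set, with no log2 step taken by the authors, as the values themselves show. The authors used Affymetrix Expression Console 1.1, per the submitters' processing notes. The summary algorithm and the scaling between arrays are not given in the sources used here. The deposited intensities ran from 0.000573 to 1054810, and 100 values in 17 probe sets lay above the largest value a 16-bit scanner writes. The deposited table holds 22625 probe sets, of which 77 are Affymetrix controls and were left out.

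Gene names came from the platform annotation of 2016, which names 1 gene for 20766 probe sets, several for 887 and none for 895. Of the 20766, 20701 matched the RefSeq gene table of assembly WBcel235 and 65 did not, and 0 symbols were changed by it. No coordinates were used, only which genes neighbour each other in that table. Each gene was represented by its probe set with the highest mean over all 47 arrays, which left 17118 genes, 2981 of them with more than 1 probe set. A probe set that names several genes was not tested in the gene counts, because its signal cannot be given to 1 of them.

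Deposited intensities were turned into log2(intensity + 1) without further scaling, so a difference in log2 understates the change of dim genes. The tests used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, and tables and plots used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A mean was fitted to each of the 9 groups of T8, T12 and T16, on 38 arrays with 29 residual degrees of freedom, and variances were moderated with eBayes. Comparisons of genotypes averaged the differences at the 3 times with equal weight. A gene was called when its Benjamini-Hochberg adjusted p over the 17118 genes was under 0.05. For Abeta against both controls a gene had to pass in each of the comparisons with the same sign. The interaction tested Abeta minus the mean of both controls at T16 minus the same at T8. Errors of differences are standard errors (SE) from limma, and errors of group levels are standard deviations (SD) between arrays.

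GFP T8 replicate 3 was much dimmer than the other 46 arrays, and it moved the median of all genes by more than 0.1 in the comparisons it entered. Differences are therefore given relative to the median difference of all genes in the same comparison. The adjusted p belongs to the unshifted difference. The number of arrays in a direction counts arrays on that side of the mean of the other group at the same time, after each array was centred on its median. The number of arrays limits the precision of every value, and the samples of a genotype and time are the replicates.

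The 28 gene lists were stress pathways, immune genes, muscle, neuronal and intestinal markers, germline, cuticle and molting genes, and metabolic and ribosomal genes. They were tested with camera, preset inter-gene correlation 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes, whereas fry, also run, tests whether the genes of a list move on balance in 1 direction and compares them with no other gene. A list is called higher or lower here by camera at an adjusted p under 0.05. Counts adjusted over the list alone used only the members of the list.

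The groups, tests, lists, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. For Abeta against both controls the rule takes up to 12 genes higher and 12 lower, with 1 sign at each of the 3 times, by the smaller of both differences. It takes 6 higher and 6 lower for each pair of genotypes, among genes that passed and had the same sign at the 3 times, and 8 of each for T16 against T8 in GFP. It also takes 4 members per called list and 2 per other list, and 17 stress, muscle, cuticle and yolk genes in any case. The probe sets used here name neither aip-1 nor hsp-16.1 alone, so 15 of the 17 are reported. Applying the first part of the rule again without GFP T8 replicate 3 was decided after that array was seen.

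A stage score per array was the projection on the T16 minus T8 change of the GFP arrays over the 500 genes with the largest statistic there, with 0 at the mean of the arrays of T8, T12 and T16 and 1 unit equal to that change. Zero, unit and genes of the scores printed were set without GFP T8 replicate 3, which was then scored with them. The covariate fitted with all arrays was set with it. Alternatives fixed in advance were quantile normalization, centring on array medians, a pseudocount of 16, leaving out the dimmest 33.3% of genes, all 22548 probe sets, the mean of the probe sets of a gene, and replicate number as a fixed or random block. Also fixed were a variance trend with robust moderation, array weights, only the groups compared, a 2-fold threshold, an adjusted p threshold of 0.01, the stage score as covariate, and leaving out each array or each replicate number. Chosen after seeing the data were 4 alternatives without GFP T8 replicate 3: the stage score, the share of probe sets under an intensity of 16, both together, and quantile normalization. Splits of the arrays into groups of the same sizes were counted over 100 drawings with seed 1, or over all 35 for 4 arrays against 4.

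The fits were tested on simulated data made for Abeta against GFP, with the spread of the real 17118 genes and 200 changed genes. With all 38 arrays, 12.1% of changes of 0.5 in log2 were recovered, 64.2% of changes of 1 and 97% of changes of 2, with 8 false calls. Without GFP T8 replicate 3 the shares were 37.9%, 79.1% and 95.5%, with 3 false calls. A first limit on the share of 4-fold changes recovered was narrowly missed with all arrays. The genes missed had a median SD of 1.395 against 0.513 for those recovered, so that limit was replaced by tests of correctness, and the draw of changed genes was redone when the order of genes was fixed.

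All 62 pairs of repeats were compared before averaging: at most 2 genes of a pair had equal values, and the SD of their differences ran from 0.443 to 1.32 in log2. The 9 arrays of T0, T4 and T20 have no repeat, entered no test and are given as values. Scan dates and batches are not given in the sources used here, so no batch was tested. The correlation of the Abeta and GFP::degron effects was set against 20 simulations of unchanged groups, because both effects share the GFP arrays.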

Results

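Expression was measured on 47 arrays in 3 strains of Caenorhabditis elegans. Of these, 16 arrays were of worms expressing GFP, 16 of worms expressing GFP::degron and 15 of worms expressing Abeta, the amyloid beta peptide that accumulates in Alzheimer's disease. A degron is a peptide that marks a protein for degradation. Worms were raised at 16 °C until early in the third larval stage, moved to 25 °C, and collected at the move (T0) and every 4 h after it up to 20 h (T4 to T20). T8 and T16 had 4 arrays per strain, T12 had 5 of GFP, 5 of GFP::degron and 4 of Abeta, and T0, T4 and T20 had 1 array per strain. Median intensity was 20.3 on GFP T8 replicate 3 and between 60.1 and 108.7 on the other 46 arrays. On that array 43.8% of probe sets lay under an intensity of 16, against 11.3% to 26.1% on the others.

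The series compares a strain that makes Abeta with strains that make other foreign proteins, to find what follows from Abeta over the hours after the upshift. The worms also grew during the experiment, and the strains did not pass the same stage at the same hour. The stage score of GFP worms went from -0.26 ± 0.205 (SD, n = 4) at T8 to 0.84 ± 0.0509 (SD, n = 4) at T16. The T8 mean holds the dim array, which scored -0.548. At T16 the score was 0.56 ± 0.24 (SD, n = 4) in Abeta and 0.10 ± 0.426 (SD, n = 4) in GFP::degron worms, whose 4 arrays lay at -0.28, 0.71, 0.04 and -0.06. The first principal component of the 38 arrays of T8, T12 and T16, after quantile normalization, held 47% of the variance.

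**Figure D1:**
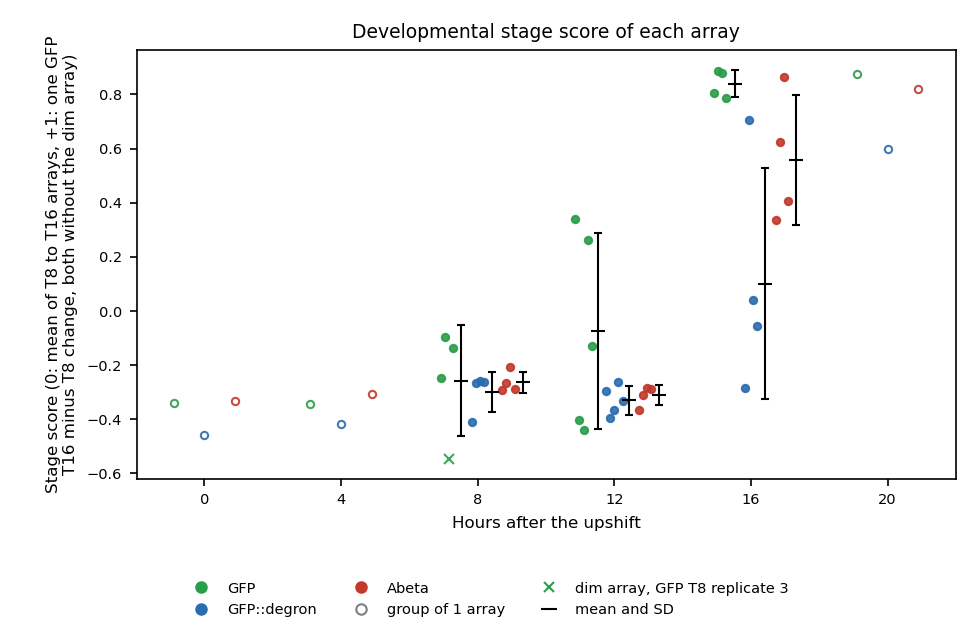
Stage score of each array (y axis; 0 is the mean of the arrays of T8, T12 and T16 and +1 is the T16 minus T8 change of GFP worms above it, both set without GFP T8 replicate 3) against hours after the upshift (x axis) in the 3 strains, with open circles for groups of 1 array, a cross for GFP T8 replicate 3 and bars for the mean and SD. At T16 the GFP arrays average 0.84, the Abeta arrays 0.56 and the GFP::degron arrays 0.10.

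Which genes set Abeta worms apart from both control strains was the first question. Over T8, T12 and T16, 7 genes passed against both with the same sign, 2 higher and 5 lower in Abeta. The higher genes were scl-24, which encodes a secreted SCP-like protein, and F14F9.5. The lower ones were F14F8.8, F15D4.5, K09C6.9, the neuropeptide receptor gene npr-28 and the cuticle collagen gene col-150.

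In log2 units relative to the median of all genes, scl-24 was higher in Abeta by 1.77 ± 0.299 (SE) than in GFP worms (adjusted p = 0.000541) and by 1.44 ± 0.299 than in GFP::degron worms (adjusted p = 0.0225). It was higher in 12 of 12 Abeta arrays each time. At T8 its log2 level was 8.09 ± 1.04 (SD, n = 4) in Abeta, 5.595 ± 1.22 in GFP and 6.39 ± 0.644 in GFP::degron worms. F14F9.5 differed by 0.37 ± 0.142 from GFP (adjusted p = 0.0472, 11 of 12 arrays) and by 0.67 ± 0.142 from GFP::degron worms (adjusted p = 0.0288, 12 of 12). F14F8.8 had the lowest Abeta values relative to both controls, -2.35 ± 0.333 against GFP (adjusted p = 0.000541) and -3.83 ± 0.333 against GFP::degron (adjusted p = 4.28e-09), in 12 of 12 arrays. Its level at T16 was 4.499 ± 0.524 (SD, n = 4) in Abeta, 6.28 ± 0.947 in GFP and 8.39 ± 0.616 in GFP::degron worms. It also was higher in GFP::degron than in GFP worms by 1.48 ± 0.327 (adjusted p = 0.00104, 12 of 13 arrays). K09C6.9 behaved alike, at -1.34 ± 0.236 (adjusted p = 0.0101) and -2.21 ± 0.236 (adjusted p = 4.55e-07).

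The other lower genes held in 12 of 12 arrays against each control. F15D4.5 stood at -1.71 ± 0.176 against GFP (adjusted p = 1.01e-05) and -1.23 ± 0.176 against GFP::degron worms (adjusted p = 0.000165). For npr-28 the values were -1.19 ± 0.176 (adjusted p = 0.00232) and -1.28 ± 0.176 (adjusted p = 0.000103), and for col-150 -1.23 ± 0.183 (adjusted p = 0.00232) and -0.86 ± 0.183 (adjusted p = 0.0224). A second, dimmer probe set of col-150, mean log2 3.79, differed by only -0.20 and -0.15. For npr-28 the levels at T8 were 4.90 ± 0.126 (SD, n = 4) in Abeta, 5.502 ± 1.03 in GFP and 6.16 ± 0.266 in GFP::degron worms.

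**Figure D2:**
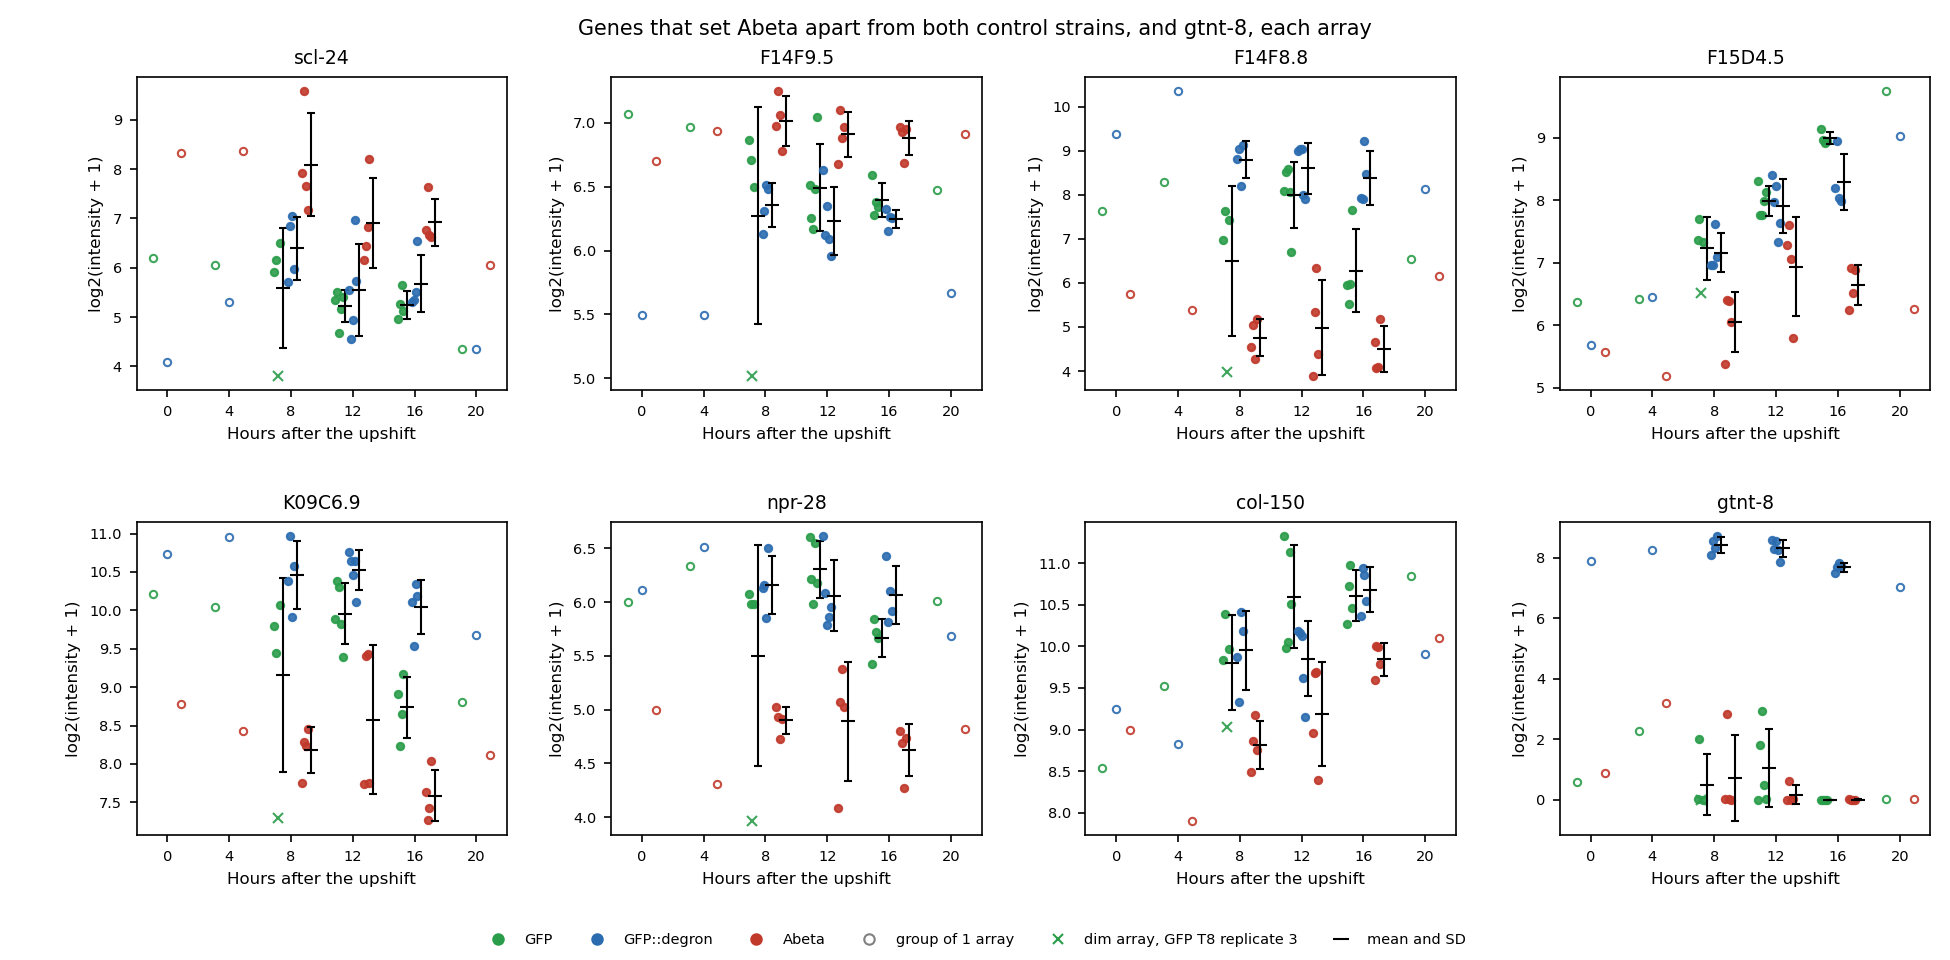
Log2(intensity + 1) on each array (y axes) against hours after the upshift (x axes) for the 7 genes that set Abeta apart from both control strains and for gtnt-8, with open circles for groups of 1 array, a cross for the dim array GFP T8 replicate 3, and bars for the mean and SD, that array included. F14F8.8 averages 4.499 in Abeta, 6.28 in GFP and 8.39 in GFP::degron at T16, and gtnt-8 averages 0.01, 0.01 and 7.68.

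Leaving out single arrays moved this count of 7 to 37 without GFP T8 replicate 3 and to 4 without GFP::degron T8 replicate 4. The 7 genes were among the 37, of which 21 were higher and 16 lower, and were also among the 22 called when the stage score was added without that array. With the stage score and all arrays the count was also 7, but 0 were higher and 7 lower. The 5 lower genes named were among these, whereas scl-24 then missed the threshold against GFP::degron worms and F14F9.5 against both strains. Under quantile normalization 68 genes passed, 40 higher and 28 lower, and under median centring 30, 14 higher and 16 lower. In the fit without the dim array the mitochondrial superoxide dismutase gene sod-3 was lower in Abeta, at -0.92 ± 0.128 against GFP (adjusted p = 0.000119) and -1.33 ± 0.124 against GFP::degron worms (adjusted p = 2.42e-08). The glutathione peroxidase gene gpx-2 was at -0.44 (adjusted p = 0.0373) and -0.69 (adjusted p = 0.000434). Lower too were drd-5, at -0.81 (adjusted p = 0.000298) and -0.78 (adjusted p = 0.000139), and F15D4.6, at -1.76 (adjusted p = 2.02e-05) and -0.85 (adjusted p = 0.019). On the higher side stood the lipase-related lips-15, at 1.25 ± 0.177 (adjusted p = 0.000104) and 0.65 ± 0.172 (adjusted p = 0.0342). With it went the C-type lectin clec-52, at 0.93 and 0.61, and mig-18, at 0.51 (adjusted p = 0.0118) and 0.72 (adjusted p = 0.000434).

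Single times gave few calls against both controls. F15D4.5 was the only gene at T16, lower in Abeta, at -2.42 ± 0.311 against GFP (adjusted p = 9.91e-05) and -1.60 ± 0.311 against GFP::degron worms (adjusted p = 0.0305). At T8 and T12 limma called 0 genes against both. An unadjusted p under 0.05 against each with the same sign was held by 44 and 213. No chance expectation was computed for these numbers, so they are not read as signal. Without GFP T8 replicate 3 limma called 0, 10 and 4 genes at T8, T12 and T16. The T12 genes were then B0454.5, drd-5, F14F8.8, F14H12.3, npr-28, sod-3 and T28A11.6 lower and F26A1.9, F54F11.1 and sfxn-2 higher, and the T16 genes F14F8.8, F15D4.5, K09C6.9 and npr-28, all lower, all named after their values were seen. Leaving out GFP T12 replicate 5, Abeta T12 replicate 3 or Abeta T12 replicate 4 gave 1, 1 and 4 genes at T12. The T16 gene was lost (0 called) without GFP::degron T16 replicate 1, 3 or 4 or Abeta T16 replicate 1, 2 or 3.

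The interaction asked if Abeta drew away from the controls from T8 to T16. Limma called 0 genes. Unadjusted, 96 of 17118 genes had p under 0.05, and 226 without GFP T8 replicate 3. Chance alone gives more, a share of 0.05, so this test was conservative and cannot exclude that genes drew away. Leaving out GFP T16 replicate 1, GFP::degron T16 replicate 2, Abeta T8 replicate 1 or Abeta T16 replicate 3 gave 4, 1, 1 and 3 calls. With the replicate number as a block the only call was the eggshell gene perm-2, at -1.84 ± 0.321 (adjusted p = 0.0108). With the stage score and without the dim array it was again, at -2.17 ± 0.328 (adjusted p = 0.00511). Chosen after its values were seen, it rose (unshifted) by 3.79 in GFP, 0.52 in GFP::degron and 0.11 in Abeta, so GFP stood out.

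Against GFP worms alone, the higher genes in Abeta included the antimicrobial peptide gene cnc-7, the heat shock gene hsp-70 and 7 of 106 neuropeptide genes. The lower ones included the yolk gene vit-1 and the eggshell gene perm-2. The lists of immune effectors and cytosolic heat shock genes were not called (adjusted p = 0.342 and 0.147), and with an estimated correlation 0 of 28 lists were. Among the caenacin antimicrobial peptides cnc-7 was higher by 2.55 ± 0.503 (adjusted p = 0.0048) and cnc-2 by 2.25 ± 0.449 (adjusted p = 0.0048). The fungus-induced gene fip-1 was higher by 2.44 ± 0.603 (adjusted p = 0.0224), srlf-34 by 2.31 ± 0.399 (adjusted p = 0.000982), C27A7.2 by 2.23 ± 0.533 (adjusted p = 0.0172) and F31F4.11 by 2.22 ± 0.485 (adjusted p = 0.0101). All were higher in 12 of 12 arrays. The lower genes besides F14F8.8 were F40G12.10 (-2.35, adjusted p = 0.0425), F07F6.1 (-2.31, adjusted p = 0.0472), the C-type lectin clec-155 (-2.19 ± 0.483, adjusted p = 0.0302), Y62H9A.4 (-2.15, adjusted p = 0.0453) and ZK1248.4 (-2.14, adjusted p = 0.0439). These 5 were lower in 11, 11, 11, 9 and 12 of 12 arrays.

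In total 210 of 17118 genes passed between Abeta and GFP, 187 higher and 23 lower, and the median of all genes lay at 0.18. With quantile normalization 1726 passed, 1111 higher and 615 lower, and with median centring 1081, 582 higher and 499 lower. With array weights more genes were lower than higher, 2543 against 2163, and with only the groups compared in the fit 10 were higher and 8 lower. With the stage score and without the dim array 108 passed, 71 of them among the 210, and of the 12 genes named only cnc-7, srlf-34 and F14F8.8 still passed. The count was 1128, 675 and 1138 without GFP T8 replicate 1, 3 or 4, 399 without GFP T12 replicate 2, and 118 or 132 without GFP T12 replicate 1 or 5. It was 119 and 113 without GFP T16 replicate 2 or 3. Among Abeta arrays it was 119, 127 and 130 without T8 replicate 1, 2 or 4, 132 and 104 without T12 replicate 2 or 3, and 103 and 122 without T16 replicate 1 or 4.

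Camera called 14 lists between Abeta and GFP, 5 higher and 9 lower, and 0 with an estimated correlation. With the stage score it called 2 and 9. Fry called 0, and 4 without the dim array. Among 106 neuropeptides 7 rose and 99 did not pass, led by nlp-62 (0.89 ± 0.222, adjusted p = 0.0123, 12 of 12 arrays) and nlp-31 (0.81 ± 0.213, adjusted p = 0.0149). Adjusted over the list alone 55 rose and 1 fell. This list and the 28 neuronal markers were higher (adjusted p = 1.06e-11 and 3.71e-06, 0.775 each with an estimated correlation). With quantile normalization 32 and 11 rose, with median centring 16 and 4. Of 28, 18 passed when adjusted over the list alone and 1 over all genes, the choline acetyltransferase gene cha-1 at 0.30 ± 0.125 (adjusted p = 0.0486, 9 of 12 arrays). Of 33 molting genes 0 passed, and 12 adjusted over the list alone. The list was higher (adjusted p = 1.95e-06, and 0.775 with an estimated correlation). The calcium handling and the p38 and JNK lists were higher too (adjusted p = 0.00397 and 0.0191, both 0.97 with an estimated correlation). Of 26 and 20 members 0 and 1 passed, and 1 and 2 adjusted over the list alone. The 1 that passed was ttm-2, a target of MAP kinase signalling under pore-forming toxin.

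Lower lists in Abeta against GFP were led by germline genes. Of 49 oocyte and germline genes 2 fell, the eggshell genes perm-2 (-1.498 ± 0.178, adjusted p = 0.000139, 11 of 12 arrays) and cpg-1 (-0.96 ± 0.189, adjusted p = 0.0301). Adjusted over the list alone 6 fell (list adjusted p = 4.84e-26). Of 77 sperm genes 0 fell, and 27 adjusted over the list alone (list adjusted p = 3.61e-36). Quantile-normalized, 27 sperm and 30 oocyte genes fell. Collagens had 1 higher (col-113) and 2 lower (col-150 and col-180) of 147, 3 and 4 adjusted over the list alone (list adjusted p = 2.18e-13). Each of these 3 lists had an adjusted p = 0.271 with an estimated correlation. The stage score, highest in GFP worms at T16, has 25 sperm genes, 2 oocyte genes and 13 collagens in its 500 genes. Of 5 vitellogenins vit-1 fell (-2.07 ± 0.427, adjusted p = 0.019), 3 adjusted over the list alone (list adjusted p = 8.84e-07; adjusted p = 0.194 with an estimated correlation). The sarcomere list of body-wall muscle was lower (adjusted p = 0.000151; adjusted p = 0.812 with an estimated correlation; lost under quantile normalization at 0.132). In it the myosin chaperone gene unc-45 was higher (0.57 ± 0.179, adjusted p = 0.0301) and unc-87 lower (-0.47 ± 0.077, adjusted p = 0.0485). Adjusted over the list alone 1 of 38 was higher and 2 were lower.

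Proteasome subunits, DAF-16 repressed targets, ribosomal proteins and oxidative phosphorylation were lower against GFP with 0 members past the threshold (adjusted p = 0.017, 0.00772, 0.0023 and 0.000212; adjusted p = 0.97, 0.743, 0.97 and 0.812 with an estimated correlation). Adjusted over the list alone 1 DAF-16 repressed target fell and 0 members of the other 3 lists. Median, mean and test differed in sign in some lists before the shift of all genes was taken off: the proteasome (0.02 and 0.01) and ribosomal lists (0.01 and 0.01) had positive medians and means, the sarcomere list a mean of 0.04, and the DAF-16 repressed targets a median of 0.01. The ribosomal test turned to higher under quantile normalization (adjusted p = 0.000432). Under quantile normalization the DAF-16 repressed and oxidative phosphorylation calls were lost (adjusted p = 0.0667 and 0.728), the first also under median centring (adjusted p = 0.107).

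Next, Abeta was set against GFP::degron worms, whose strain or lower stage score can also make a difference. In this comparison Abeta worms had far less gtnt-8 RNA and more of far-2, a gene for a fatty acid and retinol binding protein. The level of gtnt-8 was 8.42 ± 0.272 (SD, n = 4) in GFP::degron worms at T8, and 0.72 ± 1.42 and 0.50 ± 0.992 in Abeta and GFP worms. The difference of Abeta from GFP::degron was -7.83 ± 0.292 (adjusted p = 1.68e-19), and that of GFP::degron from GFP was 7.43 ± 0.287 (adjusted p = 2.35e-19, 13 of 13 arrays). For far-2 Abeta was higher by 0.96 ± 0.143 (adjusted p = 0.000456), with 12.67 ± 0.383 (SD, n = 4) in Abeta and 11.39 ± 0.552 in GFP::degron worms at T8.

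Also higher in Abeta than in GFP::degron worms were D1065.3 (2.84 ± 0.538, adjusted p = 0.00698), E01G4.6 (1.97 ± 0.441, adjusted p = 0.041) and Y17D7B.7 (0.93 ± 0.206, adjusted p = 0.0427), besides scl-24 and F14F9.5. Lower besides gtnt-8, F14F8.8 and K09C6.9 were tag-293 (-2.58 ± 0.417, adjusted p = 0.00114), C14C6.12 (-2.16 ± 0.356, adjusted p = 0.00147) and Y105C5B.20 (-1.98 ± 0.395, adjusted p = 0.0123). Each of these held in 12 of 12 arrays and passed with the stage score and without the dim array. In all 48 genes passed, 9 higher and 39 lower, around a median of all genes of -0.01. The count was 552 (99 higher, 453 lower) without GFP T8 replicate 3, an array of neither strain that adds to the shared estimate of the spread, and 103 without GFP::degron T16 replicate 2. It was 25, 30 and 28 without GFP::degron T8 replicate 4, T16 replicate 3 or T16 replicate 4, and 29 and 31 without Abeta T8 replicate 3 or T16 replicate 2. Quantile normalization gave 500, 178 higher and 322 lower.

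Camera called 12 lists between Abeta and GFP::degron, 2 higher and 10 lower, and 0 with an estimated correlation. Fry called 0, and 7 without the dim array. Of 16 DAF-16 activated targets sod-3 fell (-1.33 ± 0.211, adjusted p = 0.000911, 12 of 12 arrays), and 6 fell adjusted over the list alone (list adjusted p = 2.36e-05; adjusted p = 0.731 with an estimated correlation). Of 77 immune effectors fipr-2 fell (-1.07 ± 0.188, adjusted p = 0.00248, 12 of 12 arrays), with 1 higher and 4 lower adjusted over the list alone (list adjusted p = 0.00167; adjusted p = 0.826 with an estimated correlation). Neuropeptides and neuronal markers were lower (adjusted p = 9.98e-12 and 1.62e-05, both 0.826 with an estimated correlation). Of them 0 passed, and 2 and 0 adjusted over the list alone. Of 10 pharyngeal muscle markers 0 passed, and 4 adjusted over the list alone. The list was lower (adjusted p = 2.3e-05, and 0.731 with an estimated correlation).

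The ER unfolded protein response, p38 and JNK, autophagy, calcium handling and ribosomal lists were lower in Abeta than in GFP::degron (adjusted p = 0.00578, 0.000652, 0.0231, 0.0231 and 7.03e-05; adjusted p = 0.826 with an estimated correlation for each). Of their members 0 passed the threshold, and adjusted over the list alone only 1 calcium gene, which was higher. Autophagy was no longer called under quantile normalization (adjusted p = 0.0508) nor the ribosomal list under median centring (adjusted p = 0.271). Sperm genes had a median of 0.87 relative to all genes with 0 of 77 past the threshold, and were higher (adjusted p = 2.35e-20; adjusted p = 0.731 with an estimated correlation). So were oocyte genes (adjusted p = 0.00343; adjusted p = 0.826 with an estimated correlation), with 0 members of either adjusted over the list alone. Outside the called lists clec-17 (-1.50 ± 0.345, adjusted p = 0.0451) and the troponin I gene tni-1 (-0.41 ± 0.098, adjusted p = 0.0473) were lower.

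The comparison of GFP::degron with GFP worms had the most calls. In GFP::degron worms 71 of 106 neuropeptide genes, 22 of 28 neuronal markers and 25 of 77 immune effectors were higher than in GFP worms, and 49 of 77 sperm genes, 19 of 49 oocyte genes and 4 of 5 yolk genes lower. Camera called 19 of 28 lists, and 0 with an estimated correlation. Of 17118 genes 3092 passed, 2485 higher and 607 lower, around a median of all genes of 0.18. Besides gtnt-8, the genes with the largest higher values were C14C6.12 (3.67 ± 0.35, adjusted p = 1.39e-08), sdz-35 (3.62 ± 0.412, adjusted p = 4.86e-07), F31F4.11 (2.90 ± 0.476, adjusted p = 9.54e-05), srlf-34 (2.89 ± 0.392, adjusted p = 7e-06) and cnc-7 (2.85 ± 0.494, adjusted p = 0.000197). Each was higher in 13 of 13 arrays.

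Lower in GFP::degron were gipc-1 (-4.54 ± 0.723, adjusted p = 0.000241), ZK1248.17 (-4.52 ± 0.982, adjusted p = 0.00314), and nsph-3.1 (-4.25 ± 0.772, adjusted p = 0.000828). They were followed by C33F10.1 (-4.03 ± 0.823, adjusted p = 0.00212), nspd-1 (-3.97 ± 0.847, adjusted p = 0.00289) and the major sperm protein gene msp-49 (-3.83 ± 0.626, adjusted p = 0.000339), all in 13 of 13 arrays. With the stage score and without the dim array 680 genes passed, 530 of them among the 3092, and of these 12 genes the 5 highest and gipc-1 (-2.53 ± 0.667, adjusted p = 0.0414) still did. In that fit cnc-7 was at 1.82 (adjusted p = 0.0565), ZK1248.17 at -0.18 (adjusted p = 0.983) and msp-49 at -1.39 ± 0.437 (adjusted p = 0.0958). Quantile normalization gave 5238 calls, 2991 higher and 2247 lower, and median centring 4288, 2242 higher and 2046 lower, so the excess of higher genes shrank with both, as it did with array weights (3664 and 3314). With a 2-fold difference besides the threshold more genes were lower, 433 against 365. The stage score with all arrays acted the other way and left 2688 higher and 17 lower. No single array moved the count by over 1.5 times.

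Of the 19 lists camera called 11 were higher and 8 lower, and fry called 14, among them neuropeptides (adjusted p = 0.00119) and sperm genes (adjusted p = 0.00307). Neuropeptides stood out: 71 of 106 rose, 0 fell and 82 rose adjusted over the list alone (list adjusted p = 1.66e-19; adjusted p = 0.52 with an estimated correlation). Examples are the insulin-like genes ins-4 (1.51 ± 0.309, adjusted p = 0.000621) and ins-35 (1.41 ± 0.303, adjusted p = 0.000828) and nlp-29 (1.22 ± 0.218, adjusted p = 0.000109), an antimicrobial neuropeptide-like gene. Of 28 neuronal markers 22 rose, also adjusted over the list alone (list adjusted p = 1.64e-09; adjusted p = 0.52 with an estimated correlation). Among them were unc-25, the glutamate decarboxylase of GABA neurons (0.87 ± 0.202, adjusted p = 0.000828), and egl-3, a neuropeptide-processing convertase (0.79 ± 0.163, adjusted p = 0.000263). Pharyngeal muscle markers rose in 8 of 10, also adjusted over the list alone (list adjusted p = 0.000518; adjusted p = 0.52 with an estimated correlation), with the myosin gene myo-1 at 0.65 ± 0.185 (adjusted p = 0.00284). With the stage score and without the dim array 24 neuropeptides, 9 neuronal and 0 pharyngeal markers rose.

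Immune effectors rose in 25 of 77 and in 30 adjusted over the list alone (list adjusted p = 0.00558; adjusted p = 0.781 with an estimated correlation). Among these peptides were cnc-4 (2.01 ± 0.328, adjusted p = 6.61e-05) and fipr-26 (2.08 ± 0.355, adjusted p = 0.000115). DAF-16 activated targets rose in 8 of 16 and in 9 adjusted over the list alone (list adjusted p = 0.00206; adjusted p = 0.52 with an estimated correlation). The lysozyme gene lys-7 was at 1.46 ± 0.277 (adjusted p = 0.000281) and the metallothionein gene mtl-1 at 1.33 ± 0.367 (adjusted p = 0.00502). In the p38 and JNK list 7 of 20 rose and 17 adjusted over the list alone (list adjusted p = 8.95e-05; adjusted p = 0.675 with an estimated correlation), such as nipi-3 (0.73 ± 0.175, adjusted p = 0.000828). Of 26 calcium handling genes 13 rose and 1 fell, 18 and 1 adjusted over the list alone (list adjusted p = 0.000294; adjusted p = 0.692 with an estimated correlation). The plasma membrane calcium pump gene mca-1 was at 0.84 ± 0.209 (adjusted p = 0.00142). Heat shock genes rose in 9 of 22, also adjusted over the list alone (list adjusted p = 0.0185; adjusted p = 0.781 with an estimated correlation; 0.0665 under median centring). Autophagy and lysosome genes rose in 8 of 36, also adjusted over the list alone (list adjusted p = 0.0129; adjusted p = 0.782 with an estimated correlation). The p62 homologue sqst-1 was at 0.79 ± 0.167 (adjusted p = 0.000336) and the LC3 homologue lgg-2 at 0.65.

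Molting genes rose in 15 of 33 and in 21 adjusted over the list alone (list adjusted p = 3.08e-05; adjusted p = 0.675 with an estimated correlation). They included the nuclear receptor genes nhr-25 (0.97 ± 0.206, adjusted p = 0.000481) and nhr-23 (0.64 ± 0.238, adjusted p = 0.0155). The cytochrome P450 and UDP-glucuronosyltransferase list rose in 27 of 137 and in 28 adjusted over the list alone (list adjusted p = 0.0433; adjusted p = 0.874 with an estimated correlation). The cytochrome P450 gene cyp-32A1 was at 1.57 ± 0.255 (adjusted p = 4.48e-05).

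Sperm genes fell in 49 of 77 and in 59 adjusted over the list alone (list adjusted p = 1.59e-50; adjusted p = 0.18 with an estimated correlation). The major sperm protein gene msp-32 was at -3.77 ± 0.79 (adjusted p = 0.00261) and msp-76 at -3.71 ± 0.782 (adjusted p = 0.00268). Oocyte and germline genes fell in 19 of 49 and in 26 adjusted over the list alone (list adjusted p = 2.05e-22; adjusted p = 0.451 with an estimated correlation). The eggshell gene perm-2 was at -1.42 ± 0.174 (adjusted p = 3.05e-05) and the RNA-binding protein gene puf-5 at -1.13 ± 0.211 (adjusted p = 0.00288). Of 5 vitellogenins 4 fell, also adjusted over the list alone (list adjusted p = 9.8e-06; adjusted p = 0.18 with an estimated correlation). These were vit-2 at -3.48, vit-5 at -2.46 ± 0.541, vit-1 at -2.16 ± 0.42 and vit-6 at -1.58 ± 0.378. Collagens rose in 10 and fell in 24 of 147, also adjusted over the list alone (list adjusted p = 0.000217; adjusted p = 0.675 with an estimated correlation). The blister gene bli-1 was at -2.67 ± 0.591 (adjusted p = 0.00435) and col-49 at -2.41 ± 0.371 (adjusted p = 0.000243). The median of the collagens was 0.05 and their mean -0.17. At T16 the stage score averaged 0.10 in GFP::degron and 0.84 in GFP worms. With the score in the fit and without the dim array, 1 sperm gene fell and 1 rose, 3 oocyte genes and 0 vitellogenins fell, and 1 collagen fell and 3 rose.

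Of 31 proteasome subunits 0 fell in GFP::degron, also adjusted over the list alone. The list was lower (adjusted p = 0.00188, and 0.782 with an estimated correlation). DAF-16 repressed targets were lower with vit-2 and vit-5 fallen of 12, also adjusted over the list alone (list adjusted p = 0.0128; adjusted p = 0.566 with an estimated correlation). That call was lost under quantile normalization (0.0662) and median centring (0.0725), where 12 and 14 proteasome subunits fell. C-type lectins rose in 13, such as clec-17 (2.03 ± 0.339, adjusted p = 8.71e-05), and fell in 8 of 220, such as clec-79 (-2.76 ± 0.632, adjusted p = 0.00555), 11 and 8 adjusted over the list alone. The lectin test was toward lower (adjusted p = 0.0129, and 0.807 with an estimated correlation). Quantile normalization gave 0.0912. But median (0.08) and mean (0.04) were positive. Body-wall muscle genes rose in 4 and fell in 5 of 38, 5 and 5 adjusted over the list alone (list adjusted p = 0.0343 toward lower; adjusted p = 0.807 with an estimated correlation; 0.289 under quantile normalization). Their median was -0.04 and their mean 0.095. In that list unc-45 rose by 0.88 ± 0.176 (adjusted p = 0.000237) and the troponin T gene tnt-2 was at -0.76 ± 0.105 (adjusted p = 0.000641).

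The 9 lists not called between GFP::degron and GFP still held members past the threshold. The ER unfolded protein response had 6 of 24 higher, also adjusted over the list alone (list adjusted p = 0.0857), among them atf-6 at 0.58 and pek-1 at 0.52, and the mitochondrial one 2 of 11 (0.445), dve-1 and atfs-1. SKN-1 targets had 3 of 23 higher (0.684), fatty acid metabolism 11 higher and 5 lower of 75 (0.528) and histones 4 higher and 1 lower of 26 (0.443). HIF-1 targets and intestinal markers had 0 of 8 and 0 of 17 past the threshold (0.55 and 0.702). Adjusted over the list alone these counts stayed, except 6 lower in fatty acid metabolism. Of 34 oxidative phosphorylation genes asb-1 fell (list adjusted p = 0.0514; toward lower at 0.000172 under median centring), 0 adjusted over the list alone. Ribosomal proteins had 0 of 63 past the threshold (0.684), with a test toward higher under quantile normalization (3.06e-05) and toward lower under median centring (0.00978).

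How far the response to Abeta resembled that to GFP::degron was asked with GFP as the common reference. Across genes, the log2 differences of Abeta and of GFP::degron from GFP had a Pearson r of 0.803 and a Spearman rho of 0.722; genes are not independent replicates. Unchanged groups set against the same GFP arrays gave r = 0.493 in simulation. The simulation drew each gene independently, so shifts of many genes at once, such as by stage, are not in it. The covariance was 0.158 against 0.0336 simulated, a difference of 0.124. With the GFP arrays split so that each strain had its own, r was 0.57 and 0.629 in the 2 assignments and the covariance 0.128 and 0.135. Against GFP, genes called higher in both strains numbered 153, such as cnc-7, srlf-34 and F31F4.11, where independent lists would share 27.1, and genes lower in both numbered 14, against 0.816. The numbers without GFP T8 replicate 3 were 361 and 168, against 69.6 and 20.2 for independent lists. With split GFP arrays the calls differed between the assignments, of which the first set Abeta and the other GFP::degron worms against the GFP arrays that hold the dim one. In the first 2905 genes were called in Abeta and 494 in GFP::degron worms, with 97 higher in both and 9 lower, against 24.7 and 0.568 for independent lists. In the other 5 and 5340 were called, with 0 higher and 1 lower in both. The split arrays without the dim one gave 80 and 11 (15.3 and 1.49 for independent lists) and 97 and 35 (18.7 and 3.25), with 1 GFP T8 array on a side, assumed to vary like the other groups. In opposite directions 2 genes were called with all arrays, F14F8.8 and K09C6.9, named after their values were seen, and 6 without GFP T8 replicate 3.

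Heat shock genes were among those shared by both strains. The small heat shock protein genes hsp-16.2 and hsp-16.41 and the inducible hsp-70 were higher in Abeta than in GFP worms by 1.70 ± 0.44 (adjusted p = 0.0265), 1.83 ± 0.471 (adjusted p = 0.0258) and 1.89 ± 0.434 (adjusted p = 0.0129). Set against the GFP mean of the same time, all 3 were higher in 12 of 12 arrays. In GFP::degron worms they were higher than in GFP worms by 1.58 ± 0.433 (adjusted p = 0.0054), 2.104 ± 0.463 (adjusted p = 0.00137) and 2.05 ± 0.427 (adjusted p = 0.000848), in 13 of 13 arrays. Single GFP arrays differed: at T12, hsp-16.2 stood at 10.93 and 10.902 on replicates 2 and 3 and between 7.23 and 8.21 on the other 3, and hsp-70 at 9.41 and 9.304 against 5.97 to 6.5. The stage scores of replicates 2 and 3 were -0.403 and -0.44, and those of 1, 4 and 5 were 0.34, 0.26 and -0.13. Between Abeta and GFP::degron the 3 genes differed by 0.12, -0.27 and -0.15 (adjusted p = 0.997, 0.969 and 0.986). In level, hsp-70 stood at 7.05 ± 0.233 (SD, n = 4) at T8 and 10.07 ± 0.17 (SD, n = 4) at T16 in Abeta, and at 8.54 ± 0.777 and 9.21 ± 0.574 in GFP::degron worms. The T16 minus T8 change in Abeta was 3.05 ± 0.765 for hsp-70 (adjusted p = 0.0131), 2.78 ± 0.83 for hsp-16.41 (adjusted p = 0.0497) and 2.46 ± 0.776 for hsp-16.2 (adjusted p = 0.0705). Set against the change in GFP::degron worms, that of hsp-70 was larger by 2.37 ± 1.08, which did not pass (adjusted p = 1). Against GFP, hsp-16.2 was not called in Abeta without GFP T12 replicate 1, GFP T16 replicate 2 or 3 or Abeta T12 replicate 3, nor hsp-16.41 without any of the last 3. With the stage score and without the dim array none of the 3 passed. For hsp-16.2, hsp-16.41 and hsp-70 the differences from GFP then were 1.16 ± 0.409, 1.21 ± 0.419 and 1.495 ± 0.443 in Abeta (adjusted p = 0.158, 0.155 and 0.0919). In GFP::degron worms they were 0.74 ± 0.475, 1.12 ± 0.487 and 1.41 ± 0.514 (adjusted p = 0.255, 0.114 and 0.0744). The whole heat shock list was not called between Abeta and GFP (4 of 22 higher, adjusted p = 0.147; 0.0101 under quantile normalization).

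**Figure D3:**
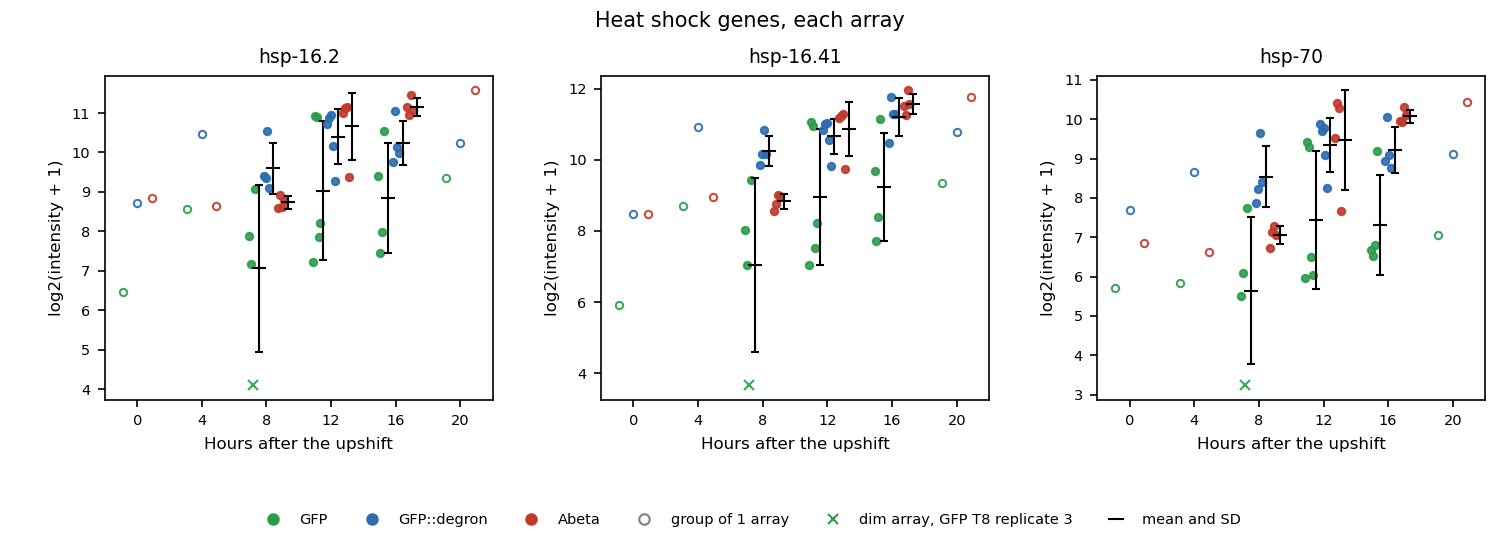
Log2(intensity + 1) of hsp-16.2, hsp-16.41 and hsp-70 on each array (y axes) against hours after the upshift (x axes), with open circles for groups of 1 array, a cross for the dim array GFP T8 replicate 3, and bars for the mean and SD. In Abeta worms hsp-70 averages 7.05 at T8 and 10.07 at T16.

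Other stress, muscle and cuticle genes named in advance gave mixed results. The superoxide dismutase gene sod-3 was higher in GFP::degron than in GFP worms by 0.48 ± 0.207 (adjusted p = 0.0242, 10 of 13 arrays). Its Abeta value of -0.85 ± 0.211 against GFP missed the threshold with all arrays (adjusted p = 0.0955). The toxin-regulated gene ttm-2 was higher than in GFP worms both in Abeta (0.79 ± 0.224, adjusted p = 0.0226, 12 of 12 arrays) and in GFP::degron worms (0.74 ± 0.22, adjusted p = 0.00443, 13 of 13). The collagen gene rol-6 was higher in GFP::degron worms (1.15 ± 0.271, adjusted p = 0.00138, 13 of 13). The ER chaperone gene hsp-4 differed by -0.17 between Abeta and GFP (adjusted p = 0.992) and the mitochondrial chaperone gene hsp-6 by -0.05. The glutathione transferase gene gst-4 differed by 0.11 (adjusted p = 0.464), ttm-1 by 0.11 (adjusted p = 0.307) and mtl-1 by 0.29 (adjusted p = 0.5). The myosin heavy chain genes myo-3 and unc-54 stood at -0.42 (adjusted p = 0.33) and -0.14. The adult collagen gene col-19 and the yolk gene vit-2 were at -1.51 ± 0.428 (adjusted p = 0.102) and -1.84 ± 0.872 (adjusted p = 0.293) in Abeta. Both were lower in GFP::degron than in GFP worms, at -2.22 ± 0.421 (adjusted p = 0.00158, 12 of 13 arrays) and -3.48 ± 0.856 (adjusted p = 0.00825, 12 of 13).

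The time course within a strain shows what changed between 8 and 16 h at 25 °C. In GFP worms 70 of 77 sperm genes, 45 of 49 oocyte genes and 4 of 5 yolk genes rose. Camera called 13 of 28 lists there, and 0 with an estimated correlation. The yolk gene vit-2 was higher at T16 than at T8 by 8.79 ± 1.54 (adjusted p = 5.94e-05), col-63 by 8.38 ± 1.52 (adjusted p = 9.36e-05) and the adult collagen gene col-19 by 5.08 ± 0.754 (adjusted p = 6.66e-06). Each was higher in 4 of 4 arrays. Other leading genes were ZK1248.17 (11.44), ZK546.3 (9.38), F55B11.2 (8.58), K03H1.12 (8.11), C40C9.3 (7.92) and F53B6.4 (7.91), and F15D4.5, one of the genes low in Abeta, was higher by 1.44 ± 0.311 (adjusted p = 0.000105). Lower at T16 were the collagen genes col-41 (-4.25 ± 0.572, adjusted p = 1.07e-05), col-54 (-2.55 ± 0.366, adjusted p = 4.43e-05) and col-90 (-2.54 ± 0.29, adjusted p = 3.92e-06), and rpi-1 (-3.13 ± 0.685, adjusted p = 0.00354). C33H5.1 (-2.47), the ligand-gated channel gene lgc-46 (-2.40), D1079.1 (-2.21) and srap-1 (-2.07) followed.

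With all arrays 2721 genes passed between T16 and T8 in GFP worms, 2622 higher and 99 lower, around a median of all genes of 0.33. Without GFP T8 replicate 3 the split was 1866 higher and 2046 lower, and 1951 of the 2721 genes stayed called; without GFP T8 replicate 4 the count was 4147. Under quantile normalization 2315 were higher and 3658 lower, and under median centring 2085 and 3353, so lower genes then were the majority. Of the 3 differences between strains in this change, GFP minus GFP::degron had 17 genes, GFP minus Abeta 2 and Abeta minus GFP::degron 1.

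Of 77 sperm genes 70 rose in GFP worms, also adjusted over the list alone (list adjusted p = 3.77e-37; adjusted p = 0.239 with an estimated correlation), with nspd-1 at 7.67 ± 1.52 (adjusted p = 0.000261). Of 49 oocyte and germline genes 45 rose, 48 adjusted over the list alone (list adjusted p = 8.75e-34; adjusted p = 0.239 with an estimated correlation). In this list perm-2 was at 3.46 ± 0.313 (adjusted p = 2.41e-09) and the maternal gene pos-1 at 3.30 ± 0.437 (adjusted p = 1.75e-06). Of 5 vitellogenins 4 rose, also adjusted over the list alone (list adjusted p = 6.11e-05; adjusted p = 0.239 with an estimated correlation). Proteasome subunits were higher with 3 of 31 risen and 0 adjusted over the list alone (list adjusted p = 0.0422; adjusted p = 0.808 with an estimated correlation; 0.0525 under quantile normalization, and toward lower at 0.41 under median centring). The collagen list, with 35 risen and 5 fallen of 147, 37 and 6 adjusted over the list alone, was not called (adjusted p = 0.706).

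Lower lists at T16 in GFP worms included molting genes, with 4 fallen and 1 risen of 33, also adjusted over the list alone (list adjusted p = 5.88e-07), led by nhr-25 (-1.76 ± 0.369, adjusted p = 0.00556). The mitochondrial unfolded protein response had 3 fallen of 11 and 4 adjusted over the list alone (list adjusted p = 0.00327). The 3 were the chaperone genes hsp-60 (-1.23 ± 0.247, adjusted p = 0.00901) and hsp-6 (-0.98 ± 0.163, adjusted p = 0.00448), and gpd-2. The list's median was 0.07 and its mean -0.07. Body-wall muscle, neuronal markers (0 of 28), ribosomal proteins (0 of 63) and oxidative phosphorylation were also lower (list adjusted p = 7.06e-06, 4.79e-05, 1.79e-09 and 2.18e-08). In muscle 1 of 38 fell, tni-1 at -0.85 ± 0.174, and 0 adjusted over the list alone. In oxidative phosphorylation 2 of 34 rose, asb-1 and ucr-2.3, also adjusted over the list alone. Quantile-normalized, 28 fell, with 24 muscle and 47 ribosomal genes. Neuropeptides had 3 risen and 1 fallen of 106, the latter flp-1 at -1.08 ± 0.238, 1 risen adjusted over the list alone (list adjusted p = 6.76e-09 toward lower). Each list so far here had an adjusted p = 0.653 with an estimated correlation. Neuronal and ribosomal lists, pharyngeal markers (0 of 10) and intestinal markers (0 of 17) had 0 members adjusted over the list alone. The pharyngeal and intestinal lists were lower too (list adjusted p = 2.13e-06 and 0.0489, but 0.318 and 0.77 with an estimated correlation). The intestinal call, with an unshifted median of 0.06, was lost under quantile normalization (0.0593). Without GFP T8 replicate 3, 58 neuropeptides, 20 neuronal markers, 8 pharyngeal markers and 14 molting genes fell.

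In Abeta worms 794 genes passed between T16 and T8, 776 higher and 18 lower, and in GFP::degron worms 70, 65 higher and 5 lower. The yolk gene vit-2 was higher at T16 in Abeta by 5.51 ± 1.54 (adjusted p = 0.03) and col-19 by 2.68 ± 0.754 (adjusted p = 0.0341). In GFP::degron worms they stood at 3.11 (adjusted p = 0.626) and 1.61 (adjusted p = 0.585). F15D4.6 was higher at T16 in Abeta (1.92 ± 0.447, adjusted p = 0.00777) and in GFP::degron worms (2.36 ± 0.447, adjusted p = 0.0114), and hsp-4 in Abeta (0.95 ± 0.238, adjusted p = 0.016). Quantile normalization gave 1620 higher and 1648 lower in Abeta and 671 and 545 in GFP::degron worms, and median centring 1255 and 1107, and 439 and 309. The Abeta count was 2122 without GFP T8 replicate 3 and 405 without Abeta T16 replicate 3. The GFP::degron count was 797 without GFP T8 replicate 3, 8, 13 and 20 without GFP::degron T8 replicate 1, 2 or 4, and 161, 2, 14 and 36 without GFP::degron T16 replicate 1, 2, 3 or 4.

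The arrays of T0, T4 and T20, 1 per strain and time, took no part in choosing the 7 genes that set Abeta apart from both controls, and their differences have no replicate check. At T0, before any time at 25 °C, 5 of the 7 genes (71.4%, exact 95% Clopper-Pearson interval 29% to 96.3%) had the same sign against both controls on these arrays. At T4 and T20 it was 6 of 7 (85.7%, 42.1% to 99.6%). At T0, relative to the median of all genes, scl-24 differed by 2.02 from GFP and 3.71 from GFP::degron, F14F8.8 by -1.97 and -4.16, K09C6.9 by -1.54 and -2.47, and npr-28 by -1.11 and -1.63. The exceptions were F14F9.5 at T0 (-0.47 and 0.68) and T4 (-0.11 and 1.29), and col-150 at T0 (0.35 and -0.77) and T20 (-0.81 and 0.13). At T20 F15D4.5 differed by -3.55 and -2.83. The median of the smaller difference, signed by the direction of each gene, was 1.11 at T0, 1.70 at T4 and 0.75 at T20, at percentiles 100, 100 and 99.99 of 10000 random lists of the same size and mean level.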

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

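The tests of the dim array, of stage as a cause for the heat shock genes and of the T0 difference in the pattern of Abeta genes and the listing of the arrays of the largest splits were chosen only after the results were seen; the splits of the arrays, the other stage tests and the neighbour test were chosen before.

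Single arrays lay far from the others of their group in 15 of 144 tests of a group in 1 of 16 measures, where chance gives about 1 in 20. GFP T8 replicate 3 had a median log2 of 4.414 against 6.44 to 6.59 on its 3 repeats, 43.8% of probe sets under an intensity of 16 against 11.7% to 14.9%, a sod-3 level of 5.505 against 7.95 to 8.37 and an npr-28 level of 3.965 against 5.98 to 6.08. GFP::degron T8 replicate 1 had 21.1% of probe sets under 16 against 13.1% to 13.9%, and a stage score of -0.4089 against -0.26 for the others. Abeta T12 replicate 4 had hsp-16.2 at 9.372 against 11 to 11.14 and hsp-16.41 at 9.738 against 11.18 to 11.30, and GFP T16 replicate 4 had hsp-70 at 9.198 against 6.53 to 6.81. The adult collagen gene col-19 was at 9.585 on GFP::degron T16 replicate 2 against 4.94 to 5.64, on the array whose stage score of 0.71 was the highest of its group. The yolk gene vit-2 was at 9.829 on GFP T16 replicate 1 against 11.45 to 11.75, F14F8.8 at 6.712 on GFP T12 replicate 5 against 8.06 to 8.59, and F14F9.5 at 6.684 on Abeta T16 replicate 3 against 6.93 to 6.97. For scl-24, GFP::degron T16 replicate 4 was at 6.542 against 5.31 to 5.51, and Abeta T16 replicate 2 at 7.627 against 6.63 to 6.77.

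The change from T8 to T16 differed between strains by a test of the difference itself. Between GFP and GFP::degron worms 17 genes passed, B0513.4, C39D10.7, C44B7.5, F14H3.6, F21H7.5, F36D1.4, T01H10.4, T19D12.5, Y57G11A.2, cdh-5, clec-87, col-90, egg-1, perm-2, perm-4, snf-5 and ssq-1. In the fit without GFP T8 replicate 3 there were 14, of which 10 were among the 17. The 7 lost were B0513.4, C39D10.7, F14H3.6, F36D1.4, T01H10.4, cdh-5 and snf-5, and the 4 new ones C33D3.3, F35F10.6, lbp-4 and set-20, all named after their values were seen. The differences of Y57G11A.2 and T19D12.5, 6.83 ± 1.11 and 6.61 ± 1.04, were the largest of the 17, and without that array they were 6.20 ± 1.12 and 6.61 ± 1.12. Between GFP and Abeta worms 2 passed, perm-2 (3.68 ± 0.442, adjusted p = 2.51e-05) and perm-4 (3.20 ± 0.55, adjusted p = 0.0149), also 2 without that array. The T16 minus T8 values of perm-2 were 3.79 in GFP, 0.52 in GFP::degron and 0.11 in Abeta worms. Values in this paragraph keep the shift of all genes. Relative to the median of all genes, perm-2 and perm-4 differed between GFP and Abeta worms by 3.28 and 2.798. Between Abeta and GFP::degron worms 1 passed, the chemoreceptor gene str-125 (4.45 ± 0.746, adjusted p = 0.0193).

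Probe sets outside the gene counts also passed. Among those that name several genes, 29 passed between Abeta and GFP, 1 between Abeta and GFP::degron and 183 between GFP::degron and GFP. Among those that name no gene, 5, 0 and 65 passed. The numbers without GFP T8 replicate 3 were 66, 16 and 236 for several genes and 15, 5 and 80 for none, and 2 that name several genes passed against both controls, where 0 did with all arrays.

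Regrouping the arrays at random tested whether chance gives counts as large. For Abeta against GFP 1 of 100 splits did, the real one, with 210 genes against at most 4 in the others. For Abeta against GFP::degron 1 of 100 did (48 against 10), for GFP::degron against GFP 1 of 100 (3092 against 1126), and for Abeta against both controls 1 of 100 (7 against 0), so chance can be excluded for these. Without GFP T8 replicate 3 the real counts of 675, 552, 4192 and 37 were each reached by 1 of 100 splits, with at most 400, 10, 474 and 2 in the others. For the change from T8 to T16, 1 of 35 splits reached the 70 genes of GFP::degron and the 794 of Abeta worms, with at most 0 in the others. For GFP worms 3 of 35 splits reached 2721, with up to 3304, so chance cannot be excluded there by this test. The other splits as large, with 3132 and 3304 genes, exchanged the dim GFP T8 replicate 3 with GFP T16 replicate 1 or 4.

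A real count of 0 is reached by every split by construction, so the 100 of 100 splits for Abeta against both controls at T8 (highest other 0) and T12 (highest other 62) and for the interaction (highest other 0) say nothing about chance. At T16 6 of 100 splits reached the 1 gene, so chance cannot be excluded there. The 62 genes of a split at T12, where the real one had 0, point to a structure of the samples: that split joined GFP T12 replicates 2 and 3 with GFP::degron T12 replicates 1 and 2. GFP T12 replicates 2 and 3 stood apart from 1 and 4 in stage score (-0.403 and -0.44 against 0.34 and 0.26) and on the first principal component (-46.7 and -45.3 against 45.2 and 32.9), where Abeta and GFP::degron T12 arrays lay between -48.5 and -39.7. The SD of the log2 differences between arrays was 1.16 to 1.32 across these pairs, 0.457 between 1 and 4 and 0.818 between 2 and 3. On replicates 2 and 3 gtnt-8 was at 1.79 and 2.92, against 7.86 to 8.58 in GFP::degron worms at T12, and F14F8.8 at 8.52 and 8.59, against 3.89 to 6.33 in Abeta worms. What sets these arrays apart besides stage was not tested. The 6 genes of a split at T16 point to a structure too, which was not identified. For counts of gene lists, 15 of 100 splits reached the 14 lists of Abeta against GFP (highest other 19), 16 of 100 the 12 of Abeta against GFP::degron (18) and 14 of 35 the 13 of the GFP time course (20), so chance cannot be excluded for those counts. Only for GFP::degron against GFP did 1 of 100 reach the 19 lists (highest other 18).

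The first pattern weighed is the large number of genes that differ between GFP::degron and GFP worms. The dim array as the cause is argued against, since the count without it was 1.36 times the count with it. Slower development of GFP::degron worms may account for much of it: across genes the difference had r = -0.783 with the T16 minus T8 change in Abeta worms, which shares no array with it. When the stage score was in the fit 680 genes were called, and 110 with the share of probe sets under 16 added; the highest other split gave 1272, the bound set before, so this test does not exclude stage as the whole cause, although only 2 of 100 splits, the real one included, gave 680 or more and the median of the others was 0. An effect of the degron-tagged protein itself, and one of the strain that carries it, stay open too and were not tested.

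The second pattern is the higher level of hsp-16.2, hsp-16.41 and hsp-70 in both Abeta and GFP::degron worms than in GFP worms. The dim array is argued against as the cause, because the smallest of the 6 unshifted differences without it was 1.44, where it had to fall below 1. For stage, the median T16 minus T8 change of the 3 genes in GFP worms was 0.86, with SEs between 0.72 and 0.759, so a loss of these transcripts as GFP worms grow cannot be told apart from no change by this value; within T12 the 2 GFP arrays with the lowest stage scores (-0.403 and -0.44) had the most hsp-70 (9.41 and 9.304), which goes with stage, and the other 3 (0.34, 0.26 and -0.13) had 5.97, 6.5 and 6.03. When the stage score was added the differences went from between 1.44 and 1.97 to between 0.89 and 1.58. The SEs went from at most 0.41 to at most 0.514. What ended the calls was not tested. A response to foreign protein shared by both strains is a candidate explanation that the design names and that was not separated from stage.

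The third pattern is the group of 37 genes that set Abeta apart from both controls without the dim array. A difference of the strain that needs no hours at 25 °C may account for many: at T0 the median gene had 0.795 of its later difference, from 1 array per strain, with 26 genes at or above 0.5, 10 under 0.25 and 8 of opposite sign. Linked neighbouring genes may account for some, as 6 of 37 lay within 10 genes of another of the same direction, against a median of 0 and a 95th percentile of 3 in 10000 random sets. These were the pairs drd-5 and npr-28, F15D4.5 and F15D4.6, and F09B9.4 and ncs-4, by gene order in WBcel235. A response to Abeta already present at 16 °C stays open, as it would also show at T0 and was not tested.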

How the results depend on the processing

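The 4 tests that combine leaving out GFP T8 replicate 3 with the stage score, the share of probe sets under an intensity of 16, both, or quantile normalization were chosen only after that array was seen; the other alternatives were planned. Of 217 named genes in 346 gene and comparison pairs, 0 passed in opposite directions in the main fit and an alternative. The signs of values that did not pass were not compared. Over the alternatives that keep all arrays they stayed on the same side of the threshold in 4100 of 4714 values, no longer passed in 400 and newly passed in 214. Over the 4 that leave out GFP T8 replicate 3 with another change the numbers were 923, 338 and 123 of 1384, and with arrays or replicate numbers left out 13802, 940 and 136 of 14878. Except where the construction of an alternative is named with its counts, the cause was not tested. Signal over background limits dim genes: 43.8% of probe sets lay under an intensity of 16 on GFP T8 replicate 3 and up to 26.1% on the others, and a gene near that level in a strain has only a bounded change there.

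Counts are given in the order Abeta against GFP, Abeta against GFP::degron, GFP::degron against GFP, Abeta against both controls, then T16 against T8 in GFP, GFP::degron and Abeta worms, unless named; a count left out stayed within 1.5 times in total, which says nothing of its split into higher and lower genes. Quantile normalization gave 1726, 500, 5238, 68, 5973, 1216 and 3268 genes, and 3, 3 and 6 against both controls at T8, T12 and T16. Median centring gave 1081 and 269 for Abeta against GFP and GFP::degron, 30 against both, 5438, 748 and 2362 over time, and 1, 6 and 4 at T8, T12 and T16. Array weights gave 4706, 1481, 6978, 247, 6195, 3689 and 2941, with 5, 92 and 58 at the 3 times and 5 for the interaction. A pseudocount of 16 gave 436 and 107 for Abeta against GFP and GFP::degron, and 1 at T12 and in the interaction. Leaving out dim genes gave 332 for Abeta against GFP, 1 at T12 and 465 for the Abeta time course, with fewer genes tested. With trend and robust moderation 1 gene passed at T12. Testing all probe sets moved no count by over 1.5 times, and the mean of probe sets moved only the single arrays at T20, to 100% of 6 genes.

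Fitting only the groups compared gave 18, 718 and 1793 for the pairs of strains, 0 at T16 against both controls, 1030 for the GFP and 1751 for the Abeta time course. A 2-fold difference besides the threshold left 94, 27 and 798 genes of the pairs of strains. An adjusted p under 0.01 left 35, 23, 1250 and 3, with 0 at T16, and 1720, 9 and 467 over time, fewer by construction.

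The stage score as covariate with all arrays gave 127 for Abeta against GFP, 2705 for GFP::degron against GFP (2688 higher and 17 lower), 44 for Abeta against GFP::degron (2 and 42), 7 against both controls (0 and 7), 1 for the interaction, 1, 6 and 1 over time and a correlation of both effects of 0.712, with 7 lists for Abeta against GFP::degron and 7 for the GFP time course. The score is built from the T16 minus T8 change of GFP worms, so it removes calls over time by construction. Without GFP T8 replicate 3 the stage score gave 108, 390, 680 and 22, 5 at T12 and 4 at T16, 1 for the interaction, 4 for the GFP and 4 for the Abeta time course, a correlation of 0.65, and 9, 11 and 7 lists for Abeta against GFP, GFP::degron against GFP and the GFP time course. The share of probe sets under 16 as covariate without that array gave 1344, 742, 4677 and 81, 39 at T12, 5 at T16, 1 for the interaction, and 4582, 853 and 2387 over time. Both covariates without it gave 66, 435, 110 and 17, 26 at T12, 5 at T16, 1 for the interaction, 0 for the GFP and 0 for the Abeta time course, and a correlation of 0.591. Quantile normalization without it gave 1324, 719, 5172, 74, 5566, 1592 and 3835, with 2, 9 and 10 at T8, T12 and T16 and 1 for the interaction.

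With an estimated correlation camera called 0 lists for each pair of strains and the GFP time course. In the order above fry called 0, 0, 14 and 5, and 4, 7, 17 and 19 without GFP T8 replicate 3.

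The labels do not say what a replicate number shares, and of 37 pairs of same-numbered arrays 17 had a correlation of their deviations over 0.1, with a range of -0.208 to 0.358, so the numbers were not taken to pair the arrays. All pairs exceeded 0.1 in 1 of 9 pairs of groups, GFP and Abeta at T16 (0.197 to 0.326). In 37 of 74 comparisons of an array with another strain it correlated best with its own number, where chance gives 17.6, a hint from the data that some arrays of a number share something. With the replicate number as a fixed block the counts were 149, 72, 3196 and 6, with 1 for the interaction where there was 0 without it, and the single arrays at T4 stood at 100% of 6 genes. With a random block, and with a block within time, 1 gene passed at T12 and 1 in the interaction.

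Leaving out 1 array or 1 replicate number at a time gave ranges of 12 to 1138 for Abeta against GFP, 12 to 552 for Abeta against GFP::degron, 1411 to 4388 for GFP::degron against GFP and 1 to 37 for Abeta against both controls. At T8, T12 and T16 the ranges were 0 to 0, 0 to 10 and 0 to 4, and for the interaction 0 to 4. Over time they were 2020 to 4147, 0 to 797 and 372 to 2122. The correlation of both effects ran from 0.747 to 0.835, and the counts of lists from 13 to 15, 9 to 15, 17 to 20 and 11 to 17. Without replicate numbers 1 to 5 in turn, Abeta against GFP gave 12, 25, 605, 54 and 115. Without numbers 1 to 4, Abeta against GFP::degron gave 12, 28, 138 and 14, Abeta against both controls 1, 2, 20 and 4, and the GFP::degron time course 33, 0, 294 and 0. GFP::degron against GFP gave 1853, 1689 and 1411 without numbers 1, 2 and 4, and the Abeta time course 457 and 372 without 2 and 4. At T12 numbers 3 and 5 gave 3 and 1, at T16 numbers 1 and 4 gave 0 and 0, and in the interaction numbers 1, 2 and 3 gave 3, 1 and 2.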

Other observations

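No test in this part was chosen after its result was seen, as the part reports values without tests.

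Heat shock and sod-3 levels on single arrays cannot date differences, as hsp-16.2 ran from 7.23 to 10.93 among GFP repeats at T12. The GFP::degron T0 array was dim (median 60.1). At T0 the log2 level of hsp-16.2 was 6.46 in GFP, 8.73 in GFP::degron and 8.84 in Abeta worms. For hsp-16.41 it was 5.92, 8.47 and 8.48, and for hsp-70 5.71, 7.68 and 6.85. At T4 the GFP::degron array was highest for all 3, with hsp-16.2 at 10.48 against 8.56 in GFP and 8.64 in Abeta worms. For hsp-70 it was 8.65 against 5.83 and 6.62. At T20 the Abeta array was highest, with hsp-16.2 at 11.58 against 9.36 and 10.24 and hsp-70 at 10.43 against 7.06 and 9.13. sod-3 was lowest in Abeta at each of the 3 times, at 7.72, 7.43 and 7.68, against 8.65, 9.32 and 8.88 in GFP::degron worms and 8.13, 8.10 and 7.76 in GFP worms.

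Adult genes at T20 followed the order of the stage scores, which were 0.88 in GFP, 0.82 in Abeta and 0.60 in GFP::degron worms. The collagen gene col-19 was at 11.65, 9.62 and 6.93 and the yolk gene vit-2 at 11.91, 10.07 and 7.42. With 1 array per strain and time these differences have no replicate check.

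gtnt-8 stood at 7.89 in GFP::degron worms at T0, when GFP and Abeta worms stood at 0.59 and 0.88, and was near 8 in GFP::degron worms at each replicated time (8.42, 8.31 and 7.68). It is thus a mark of that strain on these arrays that needed no hours at 25 °C; why was not tested.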
